A study of Mus musculus with 2 samples.

How the data were processed

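Mammary epithelial cells from Cuzd1-null mice and from heterozygous littermates were measured on 3′ expression microarrays. Per the labels' protocols, the inguinal mammary glands were taken on day 18 of pregnancy, minced, digested with hyaluronidase and collagenase with shaking, centrifuged and washed. No sort or gate is recorded. Biotin-labelled antisense RNA was made from total RNA. Per the labels, RNA from 5 mice of each genotype was pooled and each pool was hybridised to 1 array, so the comparison holds 2 arrays with 1 per genotype.

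The deposited values are 1 linear signal intensity per probe set and array, made by the authors with MAS5 in Affymetrix Expression Console version 1, per the submitters' processing notes. The genome build behind the probe sets is not given in the sources used here. Each array held values for 45101 probe sets, 64 of them controls. After the top and bottom 2% of values were left out, the mean was 150.0 intensity units on both arrays (149.952 each), so each array carries 1 global scaling factor. No further normalization between the arrays was seen in the values. Such scaling assumes that total signal is equal in both pools. Detection calls and scanner images were not analysed here.

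Gene names came from a probe table with the platform's annotation. There, 34958 probe sets had 1 gene symbol and 932 had several. A further 9160 non-control probe sets were not listed in it. Symbols were updated through Entrez IDs in the RefSeq mouse gene table, which held the IDs of 34754 probe sets. No gene was named from a probe set with several symbols. In all, 18193 genes had a probe set. No coordinates are printed because the values carry none.

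MAS5 intensities below the middle of the distribution are mostly background, so each array was floored at its own median over the 45037 non-control probe sets. This floor was 34.2 units on the heterozygous array and 32.5 units on the null array. Each gene was represented by its probe set with the highest mean signal. The log2 ratio of null over heterozygous was then taken. A gene was called measured if at least 1 array was above its floor, which held for 11893 genes, with 10610 above the floor on both. For a gene at the floor on 1 array the fold is a bound, written as "at least". Because the 2 floors differ, 93 of these 1283 genes have a ratio of the opposite sign (down to -0.07), which bounds nothing. Genes at least 2-fold apart were counted as a rule of size. With 1 array per genotype there is no replicate check, so no test was run and no p-value is given. The number of arrays limits the precision of every value.

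Spreads of 2 kinds were taken, and neither replaces the missing replicate error. The measured genes were divided into 20 bins by signal, and a robust SD of the log2 ratios (from the median absolute deviation) was taken in each. For genes with several probe sets, the ratios of the brightest and the next brightest were compared. The spread within bins holds real differences as well as noise. The comparison of probe sets holds only variation between probe sets, because both read the same 2 pools.

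Before the data were examined, 25 gene lists were fixed from general knowledge of the gland: milk proteins and fat globule, lipid synthesis, cholesterol synthesis, secretory transport, prolactin signalling through JAK and STAT5, EGF family ligands, ErbB receptors and feedback, steroid hormone and RANK, cell cycle, involution and acute phase, luminal epithelium, myoepithelium, tight junction, adipocytes, fibroblasts and matrix, endothelium, macrophages and myeloid cells, B and plasma cells, T and NK cells, skeletal muscle, erythroid cells, interferon response, dissociation and immediate early genes, unfolded protein response, and reference genes. The median log2 ratio of each list over its measured members was ranked among the medians of 10000 random lists of the same size matched on mean signal. The rank describes these 2 arrays and not the genotypes, since genes are not independent. Another 4 lists (skin keratinocytes, HSF1 targets, epithelial innate defence, antigen presentation) were added after the ratios were seen.

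The rule for naming genes was also fixed before the data were examined. It took Cuzd1, the 10 highest and 10 lowest ratios among genes above the floor on both arrays, the 5 brightest genes in each direction that were at the floor on the other array, and the measured EGF family ligands, Jak1, Jak2, Stat5a, Stat5b, Elf5, Cish and Socs2. Prlr, which the rule also held, was not analysed here. From each list it took up to 4 members with the largest ratios among those at least 2-fold apart, or the 2 brightest members where none was. Other list members given as examples were chosen after their values were seen.

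The procedure was tested on simulated data made from the real signals, with noise set to the real spread of ratios at each signal. Differences were planted in 200 genes, all above both floors with a mean signal over 200 units, so detection among dimmer genes was not tested. Of these planted genes, 96% of those with a 3-fold difference were called and 4% of those at 1.5-fold. Among all 11970 simulated genes, 103 were called with no planted difference. Of 200 simulated lists of 19 genes without a shift, 14 lay outside the central 95% of random lists. Of 20 lists shifted by 0.3 on the log2 scale, 18 lay above the 97.5th percentile.

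Alternatives were no floor, floors at the 25th and 75th percentile, ratios centred on their median, quantile normalization and loess with a span of 0.3. Others were the mean over all probe sets of a gene, and only probe sets without the endings s_at, x_at or a_at. The latter is called "without shared probe sets" below, although the ending a_at need not mark targets shared between genes. Thresholds of 1.5-fold and 3-fold, and both arrays above the floor, were also tried. Rescaling to the hybridization controls was added after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.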

Results

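Gene expression in mammary epithelial cells was compared between mice lacking Cuzd1, which encodes a protein with CUB and zona pellucida-like domains, and heterozygous littermates. The cells came from day 18 of pregnancy, shortly before birth, when the alveoli of the gland fill with secretory cells. Per the series' description, alveolar development and lactation were impaired in the null glands, and the arrays address which transcripts differed at that stage. Each genotype was measured once, as RNA of 5 mice pooled on 1 array. The maximum signal was 19898 intensity units on the heterozygous array and 18300 units on the null array. Above the floor were 11173 genes on the heterozygous array and 11330 on the null array. The 3′ to 5′ signal ratio of actin, a measure of RNA integrity, was 1.27 and 1.24, and that of the Gapdh control probe sets was 0.794 on both. With no replicate array, each difference below is a difference between these 2 pools.

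Cuzd1 itself read close to the floor on both arrays. Its probe set was below the floor in heterozygous cells (32.4 units against 34.2) and just above it in null cells (33.98 units against 32.5), a log2 ratio of -0.01 after flooring, whose sign comes from the unequal floors, and 0.07 with no floor. Where this probe set lies relative to the deleted part of the gene is not given in the sources used here. The targeted gene therefore does not check the labels, and the genotypes below are as labelled.

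Immunoglobulin transcripts were at the top of the genes higher in the null pool. Ighm, the heavy chain of IgM, read 172 units in heterozygous and 2252 in null cells, 13.1-fold higher. All 5 of its other measured probe sets were higher too, with log2 ratios of 0.28 to 3.81. Igkv8-30, a light-chain segment, was 5.27-fold higher, and Jchain, which joins IgM and IgA into polymers, was 4.25-fold higher. Of 22 probe sets annotated to immunoglobulin genes, 9 were at least 2-fold higher and 0 were at least 2-fold lower, with a median log2 ratio of 0.68. Igha, the heavy chain of IgA, had a ratio of -0.38. Immunoglobulin probe sets can bind each other's transcripts, so the single chain is uncertain. Igk and Iglv1 were at the floor in heterozygous cells and at least 6.23-fold and 3.40-fold higher in null cells, although another probe set of Igk had a ratio of -0.18.

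The remaining genes with the highest ratios had varied functions. Wfdc12, a small protease inhibitor of the whey acidic protein family, read 379 and 1298.5 units (3.43-fold). Ifi27l2a, an interferon-induced gene, was 3.25-fold higher, Ccl8, a chemokine, 3.05-fold and Adh1, an alcohol dehydrogenase, 3.04-fold. Spon2, a secreted matrix protein, was 3.13-fold higher, with a log2 ratio of 0.51 at its other probe set. Pdgfra, a growth factor receptor of fibroblasts, was 3.05-fold higher at its brightest probe set, with 0.04 at the other. AI467606 was 3.76-fold higher, but its other probe set had a log2 ratio of -0.07. Cst6, a cysteine protease inhibitor, Gm6958 and Col9a3, a collagen chain, were at the floor in heterozygous cells and at least 6.29-fold, 6.10-fold and 3.13-fold higher in null cells.

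Heat shock genes were among the lowest ratios. Dnaja4, a co-chaperone of Hsp70, read 277 units in heterozygous and 38.6 in null cells, 7.18-fold lower. Hsph1, a chaperone of the Hsp110 family, was 6.67-fold lower, at 3415 and 512 units. Hspa1a, the inducible Hsp70, was 3.84-fold lower, at 7451 and 1939 units, and its probe set can also bind the near-identical Hspa1b. Secreted inflammatory factors also appeared here: Ccl20, a chemokine, was 4.53-fold lower, Ptx3, a soluble pattern recognition protein, 4.52-fold, and Mmp12, a macrophage elastase, 3.42-fold. Arc, an activity-induced gene, was 3.94-fold lower. Csn1s2b, a casein, was 3.76-fold lower, at 3011 and 800 units. Sema3f was 5.22-fold lower with a log2 ratio of -0.21 at its other probe set. Gpaa1 was 3.81-fold lower at its brightest probe set, while its 2 others had log2 ratios of 0.02 and 0.88. At the floor in null cells were Atp2b2, Evc, Nagpa, Epgn and the keratin Krt6b, at least 4.24-fold, 3.99-fold, 3.97-fold, 3.97-fold and 3.43-fold lower.

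Across all genes, 133 were at least 2-fold higher and 123 at least 2-fold lower in the null pool, together 2.15% of the 11893 measured. Of these, 92 and 99 were above the floor on both arrays. Of all called genes, 7 of the higher and 13 of the lower genes reached 1000 units on the brighter array. The log2 ratios of genes above both floors had a median of 0.03 and quartiles of -0.16 and 0.23. Over bins of signal, the robust SD of the ratios of all measured genes ran from 0.16, among genes at or near the floor, to 0.76. Among 4722 genes with 2 probe sets above both floors, the robust SD per probe set was 0.21. This is the robust SD of the difference between the 2 ratios, divided by the square root of 2. The Pearson r of the 2 ratios was 0.44 across genes, which are not independent replicates. Where the brighter probe set was at least 2-fold apart, in 57 genes, the second was on the same side of 0 in 51 and at least 2-fold apart the same way in 17. In the simulated pair of arrays, 103 genes of 11970 were called with no planted difference. The simulated noise was set to the spread of the real ratios, which also holds real differences, so this count does not estimate the false calls here.

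The split between higher and lower genes rested on the scaling. The 9 probe sets for hybridization controls, added in equal amounts to each array by the usual protocol, had a median log2 ratio of -0.23. The 12 probe sets for poly-A controls, a separate set usually added to the RNA, had a median of -0.26, all of them below 0. Rescaling to the hybridization controls, an alternative chosen after the data were seen, moved the median of genes above both floors from 0.03 to 0.26. It gave 349 genes higher and 59 lower, 85.5% higher against 52.0% as deposited. Directions below are relative to the deposited scaling, and the percentiles of lists compare them with genes of similar signal, which a common factor moves equally.

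**Figure D1:**
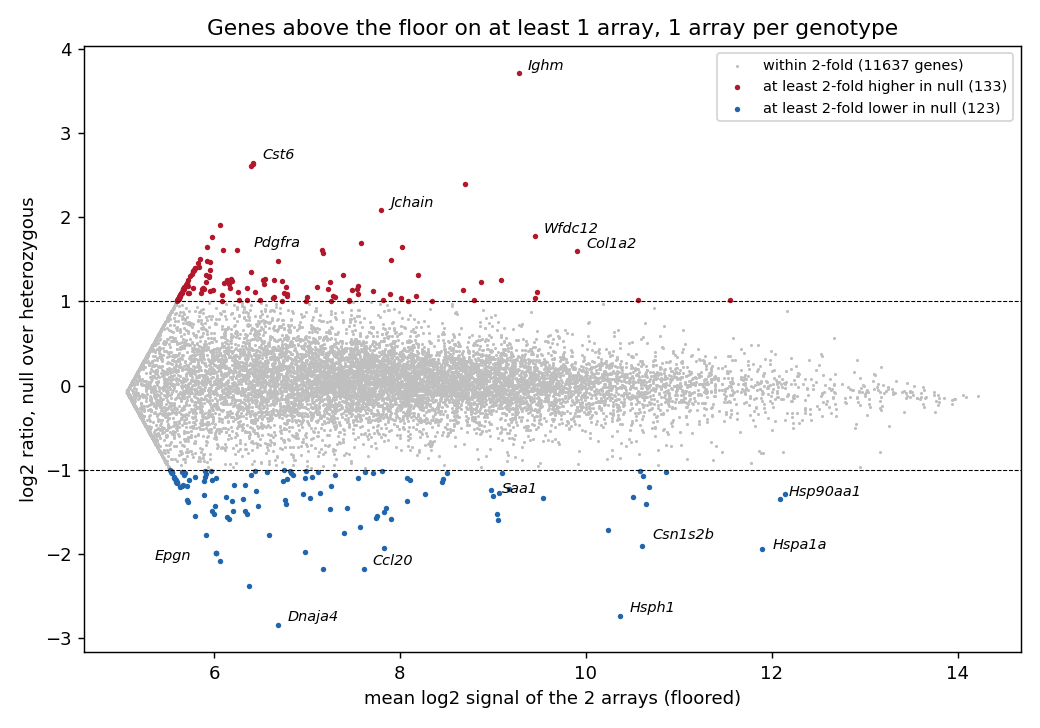
Log2 ratio of null over heterozygous signal (vertical axis) against the mean log2 signal of the 2 arrays after flooring (horizontal axis), with 1 point per gene measured on at least 1 array. Red points are the 133 genes at least 2-fold higher and blue points the 123 genes at least 2-fold lower in the null pool as deposited (349 and 59 after rescaling to hybridization controls). The dashed lines mark 2-fold, the slanted edges at the left hold genes at the floor on 1 array, and the point at the top is Ighm at 3.71.

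Milk protein and fat globule genes were lower in the null pool for all 19 measured members as deposited, with a median log2 ratio of -0.22 (quartiles -0.48 and -0.14) that became 0.00 when rescaled to the hybridization controls. Of 10000 matched random lists, 3 had a median as low. With quantile normalization the median was -0.06 (4.87th percentile), inside the central 95% of random lists. Csn1s2b was the 1 member at least 2-fold apart. Ltf, the antimicrobial iron-binding lactoferrin, had a ratio of -0.95. For Cel, the bile salt-stimulated lipase of milk, it was -0.80, and for Lalba, the regulatory subunit of lactose synthase, -0.52. Members with a mean signal over 10000 units, among them Csn2, Csn3 and Wap, had a median of -0.14 over 8 genes, and all 45 genes that bright had -0.13. The whole bin of the brightest genes, used to match the random lists, had -0.05. The rank of the milk list may therefore partly hold a trend with signal inside that bin. Dimmer probe sets of some of these genes differed more: -1.11 for Csn3 (473 and 219 units), and -3.52 and -3.55 for Csn1s2a (1448 and 126, and 991 and 84.7 units), named after their values were seen. The other 11 milk genes had a median of -0.44.

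Genes of lipid synthesis were lower for 21 of 29 measured members, with a median of -0.19 (0.05th percentile of random lists) that became 0.04 on the hybridization-control scale. Insig1, which retains the SREBP regulators in the endoplasmic reticulum and is itself their target, was 2.77-fold lower, at 254 and 91.6 units, the 1 member at least 2-fold apart. Olah, the thioesterase that releases medium-chain fatty acids, had a ratio of -0.79, Me1, malic enzyme, -0.71 and Fasn, fatty acid synthase, -0.51. Cholesterol synthesis genes had a median of -0.20 over 18 members (0.16th percentile), or 0.03 after rescaling. Within that list, Tm7sf2, a sterol reductase, was 2.06-fold lower. Mvk, mevalonate kinase, was at the floor in heterozygous cells and at least 2.63-fold higher, with 0.25 at its other probe set. Secretory transport genes had a median of -0.16 over 20 members (1.19th percentile), or 0.07 after rescaling, with 2 members at least 2-fold lower. These were Atp2b2, the calcium pump of the apical membrane, with -1.01 at its other probe set, and Aqp3, a water and glycerol channel, at 396 and 184 units (2.15-fold).

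EGF family ligands, which bind the ErbB receptors, had the lowest median of the 25 lists. The median log2 ratio was -0.68 over the 8 measured of 11 listed members (quartiles -0.90 and -0.06), and 0 of 10000 random lists were as low. The submitters' labels name this family as a topic of the study, so the list is not independent evidence of its direction. Epgn was below the floor in null cells (129 and 24.1 units, at least 3.97-fold lower), as were Ereg (72.1 and 22.3 units, at least 2.22-fold) and Nrg1 (51.2 and 22.9 units). Egf read 163 and 92.2 units, a ratio of -0.82, and Tgfa 112 and 69.3 units, a ratio of -0.70. The robust SDs among genes of similar signal were 0.37 and 0.42. The ratio was 0.01 for Hbegf, -0.08 for Btc and 0.40 for Nrg2. Areg, which no probe set names here, was not analysed here, and Nrg3 and Nrg4 were below the floor on both arrays. Over the 5 members above both floors, a filter that leaves out Epgn, Ereg and Nrg1, the median was -0.08. With the floor at the 75th percentile, which left 2 members and makes ratios of dim genes smaller, the median was -0.06. ErbB receptors and their feedback genes had a median of 0.04 over 17 members (59.7th percentile), none of them 2-fold apart. The brightest, Errfi1 and Phlda1, had ratios of 0.16 and 0.14.

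The prolactin pathway, which drives alveolar differentiation through JAK2 and STAT5, had members on both sides of 0. Its median was -0.02 over 23 members (37.1th percentile), while the mean was above 0 at 8.06e-05. After rescaling to the hybridization controls the median was 0.21. Jak1 had a ratio of -0.00, Jak2 of -0.04, Stat5a of -0.04 and Stat5b of 0.26. Elf5, a transcription factor of the alveolar lineage, had -0.15. The feedback inhibitors Cish and Socs2 had -0.23 and -0.01. Igf2, a growth factor, was the 1 member at least 2-fold apart, at 124 and 282 units (2.28-fold higher). Ghr, the growth hormone receptor, had -0.84 (-1.08 and -0.71 at its other probe sets) and Id2 -0.60 (-0.66 and -0.53), both named after their values were seen. Steroid hormone and RANK genes had a median of 0.20 over 8 members (86.7th percentile), with 0.24 for Cxcl12 and -0.18 for Tff1. Cell cycle genes had 0.11 over 36 members (84.5th percentile), or 0.34 after rescaling, with -0.08 for Pcna and 0.05 for Mcm7. No member of either list was 2-fold apart.

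**Figure D2:**
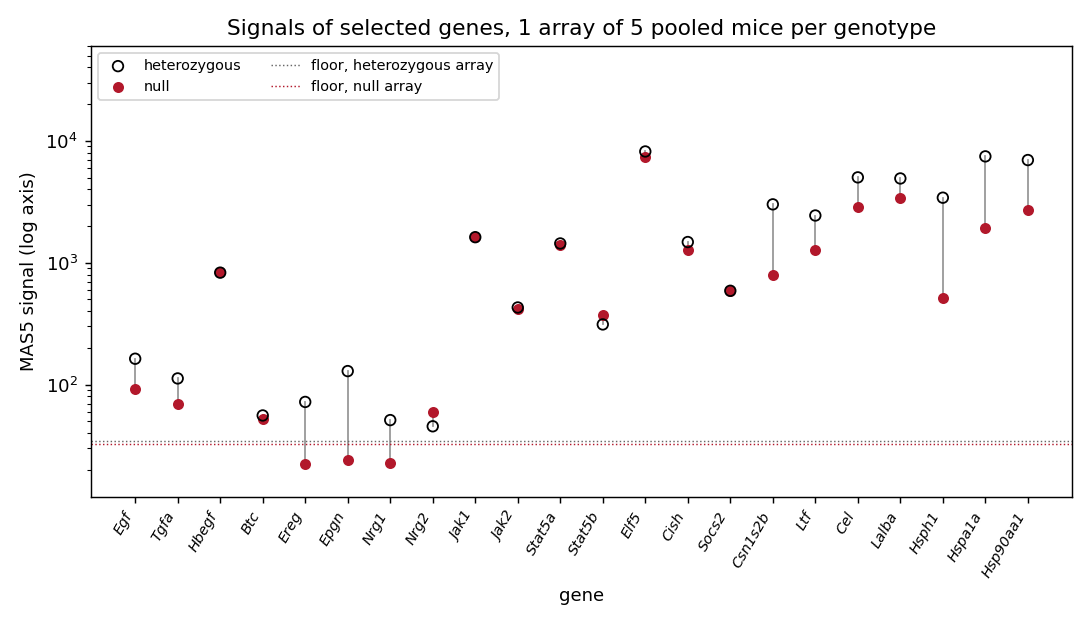
Deposited MAS5 signals (vertical log axis, intensity units) of EGF family ligands, prolactin pathway genes, milk genes and heat shock genes on the heterozygous array (open circles) and the null array (filled circles), each 1 array of 5 pooled mice, with dotted lines at the 2 floors. Epgn, Ereg and Nrg1 lie below the floor on the null array, Jak1 and Stat5a overlap, and Hsph1 reads 3415 and 512 units.

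The luminal list had a median of 0.03 over 18 members (76.5th percentile), or 0.25 after rescaling to the hybridization controls, with 0.22 for Krt18 and -0.18 for Cd24a. Tight junction genes had 0.16 over 12 members (95.9th percentile), with 0.08 for Cldn3 and 0.15 for Tjp1. No member of either list was 2-fold apart, but members lay on both sides of 0, among them Cldn1 (0.68), Pard6b (-0.56), Marveld3 (-0.56), St14 (-0.52) and Elf3 (-0.51), named after their values were seen. Myoepithelial genes had a median of -0.08 over 14 members (13.7th percentile), or 0.14 after rescaling to the hybridization controls. Within this list the basal keratins Krt15 and Krt17 were 3.22-fold and 2.93-fold lower, while the contractile genes Acta2 and Myh11 had ratios of -0.11 and 0.01.

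The medians of fibroblast, endothelial, myeloid and B cell genes were higher in the null pool at every scaling tried. Fibroblast and matrix genes had a median of 0.51 over 19 members (quartiles 0.26 and 0.82), higher in 18 of them, and 0 of 10000 random lists were as high. Col1a2, a chain of type I collagen, read 553 and 1673 units (3.02-fold), with 1.80 at its other probe set, and Pdgfra was the other member at least 2-fold apart. Col1a1, the partner chain, had a ratio of 0.06 and Postn, a matrix protein, -0.37. Endothelial genes were higher in all 15 members, with a median of 0.42 (quartiles 0.33 and 0.57) and 0 random lists as high. Vwf, von Willebrand factor, was 2.49-fold higher, at 106 and 264 units. Macrophage and myeloid genes had 0.29 over 16 members (99.9th percentile), none of them 2-fold apart, with 0.33 for Lyz1 and -0.15 for Cd14. B and plasma cell genes had 0.58 over 9 members (99.9th percentile), 3 of them at least 2-fold higher: Ighm, Jchain and Mzb1, a plasma cell chaperone, at least 2.16-fold. Only 5 members were above both floors. Apart from Igha, the remaining members were dim, among them Cd22 (38.3 and 67.0 units) and Ms4a1 (21.9 and 51.1 units), whose ratio is the median.

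Adipocyte markers went the other way, with a median of -0.30 over 10 members (0.36th percentile), or -0.02 over 5 members with the floor at the 75th percentile (44.0th percentile). Adipoq, adiponectin, was below the floor in null cells, at 66.6 and 29.2 units (at least 2.05-fold lower), and Fabp4, a fatty acid binding protein, had a ratio of -0.15. T and NK cell genes had a median of 0.14 over 8 members (81.6th percentile), with 0.19 for Gzma and 0.11 for Nkg7. Skeletal muscle genes had 0.18 over 5 (94.1th percentile), with 0.27 for Mb and 0.18 for Acta1. Erythroid genes had -0.07 over 3 members near the floor (46.5th percentile), among them Hbb-b2 and Hba-a2, but 0.36 with the floor at the 25th percentile and 0.80 with no floor, so no direction is given.

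**Figure D3:**
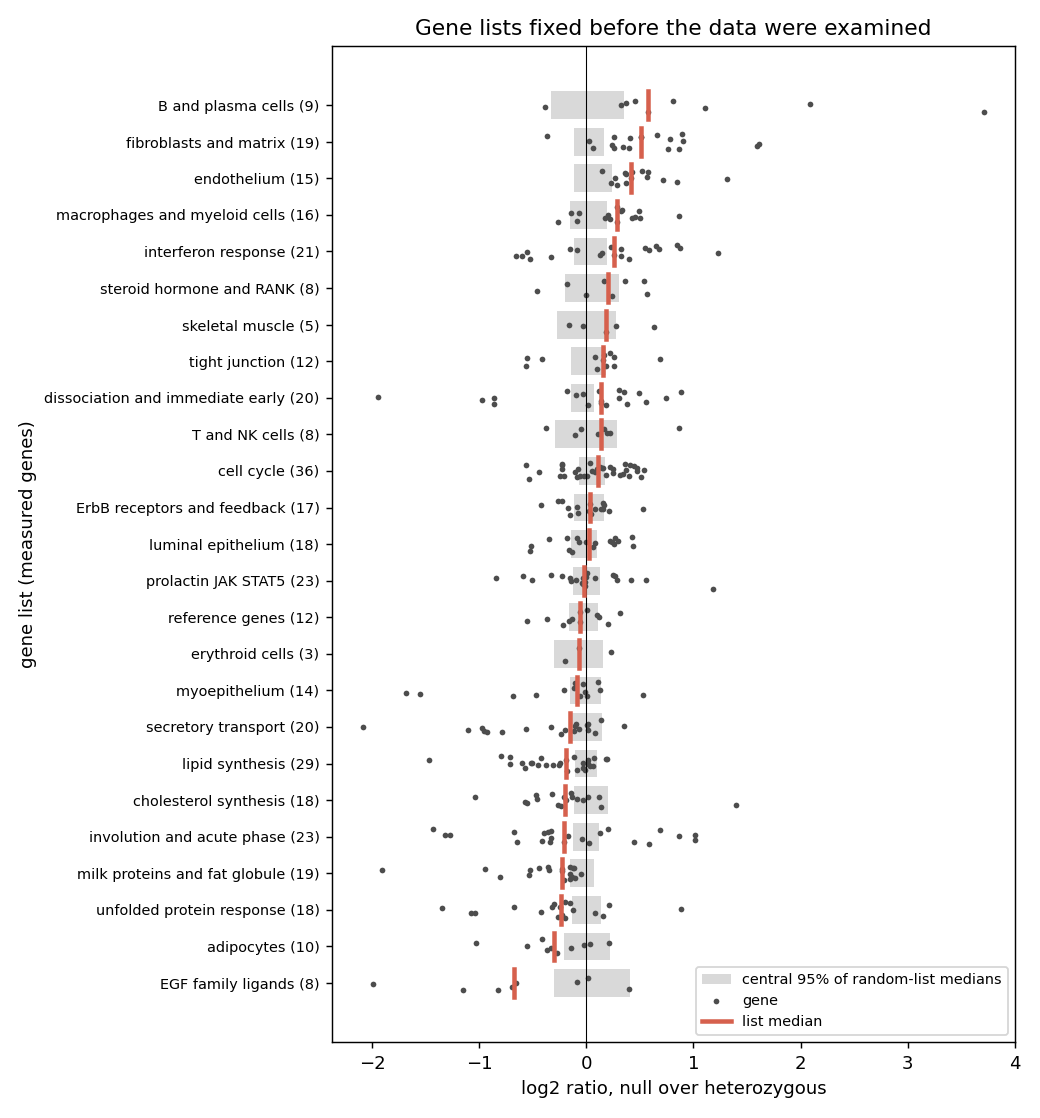
Log2 ratios of null over heterozygous signal (horizontal axis) for the 25 gene lists fixed before the data were examined, with the number of measured genes in brackets. Black points are genes, red bars are list medians as deposited and grey boxes are the central 95% of medians of 10000 matched random lists, so that fibroblasts and matrix (0.51) lie right of their box and EGF family ligands (-0.68) left of theirs. After rescaling to the hybridization controls the medians of milk, lipid synthesis, cholesterol synthesis, secretory transport and involution genes lie at 0.00 to 0.07.

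Interferon response genes had a median of 0.26 over 21 members (99.7th percentile), with 14 above 0. Oasl2, an antiviral synthetase-like gene, was 2.34-fold higher, and Tap1, a peptide transporter, had a ratio of 0.88, while Rsad2 had -0.53. Immediate early genes, which are induced when tissue is dissociated, had a median of 0.14 over 20 members (99.9th percentile) but a mean of -0.02, with Hspa1a, a member of that list, 3.84-fold lower. Unfolded protein response genes were lower for 14 of 18 members, with a median of -0.24 (0.04th percentile) and -0.01 after rescaling. Chac1, a glutathione-degrading enzyme, was 2.55-fold lower, Dnajb9, a co-chaperone, 2.11-fold and Herpud1, a component of protein degradation, 2.06-fold. Of the 4 members above 0, Pdia4 had the highest ratio, 0.88 (84.1 and 155 units).

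Involution and acute phase genes had a median of -0.21 over 23 members (0.10th percentile), or 0.02 after rescaling, with members on both sides of 0. They lay outside random lists under 4 of the 7 alternatives that can alter this rank. The acute phase proteins Saa3, Saa1 and Saa2 were 2.69-fold, 2.49-fold and 2.42-fold lower, and share similar sequence. Lif, the cytokine that starts involution through STAT3, was 2.02-fold higher, at 1065 and 2149 units. Igfbp5, an involution marker named after its value was seen, read 2122 and 4278 units, a log2 ratio of 1.01. Reference genes had a median of -0.06 over 12 members (35.4th percentile), or 0.17 after rescaling, with -0.17 for Eef1a1 and -0.06 for Actb. Of the 25 lists, 14 lay outside the central 95% of their random lists, 6 above and 8 below.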

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

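Probe sets without a single named gene were left out of the comparison, and some of them differed between the pools. Of 10092 such probe sets, 3206 were above the floor on at least 1 array. At least 2-fold higher in the null pool were 34 of these, and 61 were at least 2-fold lower. Which genes they measure was not analysed here, and no explanation was tested.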

How the results depend on the processing

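Rescaling to the hybridization controls was chosen after the data were seen, and the other alternatives before. Counts of genes at least 2-fold higher and lower were 133 and 123 as deposited, and 1676 and 1883 with no floor, 666 and 817 with the floor at the 25th percentile, and 24 and 39 at the 75th. They were 693 and 586 at 1.5-fold and 16 and 21 at 3-fold, which follows from the rules themselves. With controls as the scale they were 349 and 59. The low floors and the looser threshold kept all 133 and 123 genes, and the control scale kept the 133 higher and 59 of the lower ones. Dim signals limit the calls, since the robust SD of ratios reached 0.76 just above the floor and was 0.19 among the brightest genes.

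Rescaling to the controls raises every gene by a common factor. Among lists outside the central 95% of random lists as deposited, it turned the sign of the medians of milk (0.00428), lipid synthesis (0.036), cholesterol synthesis (0.030), secretory transport (0.072) and involution genes (0.019), and, among lists inside it, of prolactin signalling (0.21), myoepithelium (0.14), erythroid (0.16) and reference genes (0.17). It moved EGF family ligands to -0.45, cell cycle to 0.34, luminal epithelium to 0.25 and Cuzd1 to 0.22. The milk median was -0.064 with quantile normalization (4.87th percentile, inside the central 95%), -0.13 with loess, -0.36 as the mean over probe sets and -0.44 without shared probe sets. The last setting left out the bright a_at probe sets of Csn1s1, Csn1s2a, Csn2, Wap and Glycam1. Its milk median therefore covers other members and probe sets, and is not a check of shared targets alone. Without shared probe sets the lipid median was -0.26, the luminal median -0.069, and AI467606 and Gpaa1 turned to -0.074 and 0.015. With the floor at the 75th percentile the lipid median was -0.25 and the EGF median -0.056 over 2 genes (26.5th percentile). The cause was not tested.

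Over all list medians, counted over lists and settings, 201 stayed within the spread of their random lists, and 53 moved by more. The other 5 are the sign changes of lists outside the central 95%. Another 11 sign changes, in 5 lists inside it, are counted with the 201 and 53. For named genes, 385 values stayed within the spread of genes of similar signal, 56 moved by more and 2 changed sign. Fibroblast (0.50 to 0.55), endothelial (0.37 to 0.50), macrophage (0.25 to 0.33), B cell (0.58 to 1.65), interferon (0.24 to 0.32) and unfolded protein response genes (-0.26 to -0.19) lay outside the central 95% of random lists under all 7 alternatives that can alter this rank, leaving out the common factors of centring and control scaling. So did lipid synthesis, cholesterol synthesis, secretory transport and immediate early genes. Milk genes, EGF family ligands and adipocyte genes (-0.35 to -0.02) did so under 6 and involution genes under 4. Of the lists drawn up later, HSF1 targets and innate defence did so under 7, antigen presentation under 6 (96.8th percentile without shared probe sets) and skin keratinocytes under 6 (-0.19 and 10.7th percentile with no floor). Because these lists were drawn up after the ratios were seen, their ranks are not independent support. The 14 innate defence members not seen before lay at the 17.7th percentile as deposited, inside the central 95%. No paired analysis was possible because each genotype has 1 pooled array, so no array could be left out either.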

Other observations

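Chosen after the results they bear on were seen were the tests on adipocyte markers, on cell number, on immediate early genes, on the EGF ligand median and on control saturation. The 4 gene lists used here were also drawn up after the ratios were seen.

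Antigen presentation genes were higher in the null pool for all 14 measured members, with a median log2 ratio of 0.21 (99.8th percentile of matched random lists) and 0.44 after rescaling to the hybridization controls. None was 2-fold apart at its brightest probe set. Tap1, which carries peptides into the endoplasmic reticulum, had 0.88, and the immunoproteasome subunits Psmb9, Psmb10 and Psmb8 had 0.85, 0.76 and 0.59. The class I heavy chains H2-K1 and H2-D1, whose probe sets can bind related H2 transcripts, had 0.03 and 0.01, and their other probe sets 0.38 to 1.08 (3) and -0.30 to 0.42 (4). Over the 11 members whose ratios had not been seen when the list was drawn up, the median was 0.19 (99.3th percentile), with 11 above 0. This fits the hypothesis that the group is higher in this pool, although without shared probe sets, which left 8 members, the full list was at the 96.8th percentile. Macrophage genes were higher too (0.29), and leukocytes may carry part of it.

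Epithelial innate defence genes had a median of -0.38 over 22 members, with 0 of 10000 random lists as low and -0.15 after rescaling. At least 2-fold lower were 6 members, among them Ccl20, Ptx3, Saa3 and Ccl28, a mucosal chemokine at 135 and 48.2 units (2.81-fold). This did not extend to the group. The 14 members not seen before had a median of -0.058 (17.7th percentile), with 7 below 0, and Tnf, an inflammatory cytokine, had a ratio of 0.90. The hypothesis of a lower defence programme was therefore not borne out beyond the genes that prompted it.

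Heat shock genes were lower in the null pool as a group. HSF1 targets had a median of -0.72 over 23 members, 21 of them below 0 and 7 at least 2-fold lower, with 0 of 10000 random lists as low and -0.49 after rescaling. Hsp90aa1, the inducible Hsp90, read 6952 and 2721 units (2.55-fold lower). Against a few single genes stands the median of -0.49 over the 17 members not seen before, 15 of them below 0. Harsher dissociation of the heterozygous tissue, if it raised immediate early genes along with heat shock genes, should raise both sets there. The immediate early median was instead 0.14 (99.9th percentile), or 0.16 over the 18 genes other than Hspa1a and Hspa1b. Of these, 5 were below 0, among them Egr2 and Myc (both -0.86), and Arc, outside the list, was 3.94-fold lower. The median cannot exclude dissociation as a cause, because the 2 sets need not respond alike. A difference in temperature or handling between the pools, or an effect of genotype on HSF1 targets, may account for the lower heat shock genes. Neither was tested and both are confounded with the single array per genotype.

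Stromal, endothelial and B cell genes were higher in the null pool. A faulty choice of probe set is argued against by the other probe sets of the fibroblast and endothelial genes, of which 89.5% (17 of 19) were above 0. A lower share of epithelial cells should raise the other cell types alike. The adipocyte median was -0.30 (0.36th percentile), -0.33 with the floor at the 25th percentile and -0.35 with no floor, beside the fibroblast median of 0.51. The adipocyte median cannot decide this, because it rests on dim markers such as Adipoq (66.6 and 29.2 units) and Plin4 (85.0 and 57.9 units). Luminal genes, which a lower share should lower, had a median of 0.03 (76.5th percentile), with 9 of 18 members above 0. Milk genes had -0.22, and T and NK cell genes 0.14 (81.6th percentile). A luminal fall within the range of its random lists (-0.14 to 0.10) would not stand out. A lower share therefore stays open, and a lower share together with a loss of fat cells in centrifugation was not tested. Brighter adipocyte genes went both ways, with a median of -0.02 over 5 genes with the floor at the 75th percentile. Among them Pnpla2 had -0.42 and Lipe 0.22. More fibroblasts, vessels and B cells in the null gland, or higher expression per cell, may also give these values, and cannot be told apart because the arrays hold no value that separates cell number from expression.

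EGF family ligands had a median of -0.68, and the keratins Krt6b, Krt15 and Krt17 were each at least 2-fold lower. The ligand median lay below random lists of the same signal (-0.30 to 0.41), also with the floor at the 25th percentile (-0.57) and with no floor (-0.71). These ranks cannot exclude noise of dim probe sets, because the labels name this family as a topic and it may have been singled out on these same arrays. The ligand median also rests on dim members: the 5 above both floors, without the 3 at the floor in null, had -0.08. The 2 left with the floor at the 75th percentile had -0.056 (26.5th percentile). Skin carried into the heterozygous pool may have added such transcripts. Skin keratinocyte genes had a median of -0.46 over the 9 of 23 listed genes that were measured (0.05th percentile), or -0.19 over 21 with no floor (10.7th percentile). On the heterozygous array, 3 of 6 skin differentiation genes exceeded 100 units (Sbsn 1569, Dmkn 471, Krt10 155). Lor, outside those 6, read 110.5 units, and 82.3 on the null array. Sbsn and Dmkn were bright on the null array too (1140 and 437 units, Krt10 85.7), so exceeding 100 units does not by itself mark the heterozygous pool. Against skin stand Krt1 (13.8), Krt2 (1.38) and Krtdap (24.95), abundant in skin and below the floor of 34.2 on the heterozygous array. Sbsn and Dmkn are also known from other epithelia. With values on both sides, skin and genotype cannot be told apart here.

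The 100 measured genes nearest to Cuzd1 in the RefSeq mouse gene order had a median absolute log2 ratio of 0.20, within the 0.17 to 0.27 of random lists. Of these, 3 were at least 2-fold apart (Bag3, Armc5 and Fam53b, named after their values were seen). Bag3, lower in the null pool, is also a member of the HSF1 target list. The brightest hybridization control, cre, had a median log2 ratio of -0.25 at up to 12663 units, against -0.23 for the dimmer bioB, bioC and bioD. Milk genes reached 19898 units, above these controls, so compression at the top of the range was not excluded.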
